A study of Zea mays with 2 samples.

How the data were processed

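MH-seq maps MNase hypersensitive sites, the stretches of chromatin that micrococcal nuclease (MNase) cuts most readily. The libraries analysed were replicates 1 and 2 of a single group: leaf of 10-day-old maize (Zea mays) plants of the inbred line B73, the line behind the maize reference genome. Per the labels, both libraries come from formaldehyde-fixed nuclei treated with 100 U of MNase. The protocol calls this the light digestion and also describes DNA taken from a heavy one of 900 U, which neither library is labelled with. DNA fragments of 40 to 100 bp were recovered from a gel. Per the labels' protocols, leaf tissue was pooled from 10 plants. The labels do not say whether the replicates are separate collections, so the spread between them may be technical. There is no untreated, naked-DNA or second-tissue group, so no comparison between conditions was possible.

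The data are 3 peak lists, one per replicate and one named as merged. The merged list is the authors' single list for both replicates; how they combined the libraries is not given in the sources used here. Per the submitters' processing notes, the tools include fastp 0.20.0, Bowtie2, SAMtools 1.5, MACS2, ChIPseeker and deepTools, and the genome build is B73 RefGen_v4. Settings and thresholds are not given in the sources used here. Each peak carries the fold enrichment over background deposited by the authors, a deposited −log10 p and −log10 q, and the summit position. The deposited score equals 10 times the −log10 q cut to a whole number, except in 7 peaks of replicate 1 and 3 of replicate 2, and was not used further. No peak in any list has a fold enrichment below 5, and the lowest −log10 q was 5.92 in replicate 1, 6.13 in replicate 2 and 8.95 in the merged list. Fold enrichment and q are the peaks' own values and were used only to describe, rank or filter peaks within a list. Read totals are not in these lists, so the depth of each library is unknown; a replicate sequenced more deeply would yield more peaks at the same threshold.

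All peaks lie on chromosomes 1 to 10. Positions are 1-based and on B73 RefGen_v4. The gene table at hand is of another assembly (Zm-B73-REFERENCE-NAM-5.0), and no genome sequence was used. Peaks were therefore not assigned to genes, and the planned comparisons with annotated features, gene starts, gene lists and sequence motifs were not run. Chromosome lengths were taken as the last peak end in any list, which is a lower bound of the true length, and they sum to 2105.9 Mb.

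Peaks of both replicates were called shared when they overlapped by at least 1 bp. The overlap was set against 1000 circular shifts of the replicate 2 peaks within each chromosome, in a one-sided permutation test whose smallest p is 0.001. Shares carry Wilson 95% intervals, which cover counting error only, since peaks are not independent replicates. Peak density at the chromosome ends (the outer 20% at each end) was compared with the middle 20% by an exact two-sided sign-flip permutation test over the 10 chromosomes, whose smallest p is 0.00195. Clustering was measured as the share of summits whose next summit lies within 1 kb, against 1000 uniform placements in each chromosome. Pairs of summits were counted by distance in each list, with exact binomial intervals for ratios of counts. Quintiles are 5 equal groups of peaks ranked by fold enrichment within a list. Peaks under 130 bp are called narrow; that limit was set at the dip of the width distribution after the widths were seen. The 10 merged peaks with the highest fold enrichment are named, by a rule set before the data were examined. The overlap, end-to-middle density and 1 kb clustering tests were also set before then. The windows, peak-free stretches, distance classes and width classes were chosen after the data were seen, as were the comparisons of density by strength, by width, in isolated peaks and at each end singly, placement within the same 1 Mb windows, the comparison of narrow and wider peaks and the tests of strong peaks in the middle of chromosomes. Narrow and wider merged peaks were compared within 200 equal groups ranked by fold enrichment, with 1000 permutations of the width class within groups (two-sided); its p treats peaks as independent, which they are not.

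The alternatives set beforehand include a stricter overlap (50% of both peaks, or summits within 50 bp), −log10 q of at least 5 or 10, equal numbers of strongest peaks, joining of peaks within 100 bp, uniform placement, each replicate's list in place of the merged list, merged peaks overlapped by both replicates, and other distances and chromosome parts. The procedures were tested on simulated peaks. For replicate overlap, a planted share of 60% was recovered as 60.6% in a list of 60258 peaks. For density, a planted log2 ratio of 1 was recovered as 0.997 with 63644 peaks. The planted overlaps were slightly moved copies of replicate 1 peaks, and the planted density used the same chromosome parts as the measure. Both therefore check the counting, not the behaviour with the variation of real replicates. For spacing, 60518 uniformly placed peaks gave 1.01 times the expected share. The value was 0.781 times once overlapping peaks were left out (60139 peaks), so that exclusion alone lowers the measured clustering. Splitting of one region into several peaks would raise it and was not simulated, so the direction of the net bias is unknown. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.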

Results

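MNase hypersensitive sites were mapped in leaf of 10-day-old B73 maize by MH-seq, in which short fragments freed by MNase are sequenced and regions rich in them are called as peaks. The data comprise 2 replicates of one group and a list of peaks for both replicates merged. Replicate 1 held 74443 peaks and replicate 2 held 60518, a mean of 67481 ± 9847 (SD, n = 2). The merged list held 66801 peaks. The series title places this assay in a study of types of open chromatin in maize and their relation to transcription, and the lists answer where hypersensitive sites lie, how large they are and how well they recur.

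Hypersensitive sites were short and occupied under 1% of the genome. The median peak width was 185 bp in replicate 1 and 184 bp in replicate 2 (mean 184.5 ± 0.707 bp, SD, n = 2), and 220 bp in the merged list. Peaks covered 15.7 Mb in replicate 1, 12.6 Mb in replicate 2 (mean 14.1 ± 2.20 Mb) and 16.4 Mb in the merged list, the last being 0.780% of the 2105.9 Mb spanned by the 10 chromosomes. The widest merged peak measured 1333 bp and the narrowest 31 bp.

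Peak widths fell into 2 groups. In replicate 1 the most populated 20 bp bin was 80 to 99 bp, with 10842 peaks, counts dropped to 3942 peaks at 120 to 139 bp, and a second maximum of 4922 peaks stood at 180 to 199 bp. Peaks under 130 bp made up 34.2% of replicate 1, 31.6% of replicate 2 (mean 32.9% ± 1.85, SD, n = 2) and 22.8% of the merged list. The fragments recovered for sequencing were 40 to 100 bp long. Narrow merged peaks had a median fold enrichment of 5.83 and wider ones 8.20. In the weakest quintile of merged peaks 50.3% were narrow, against 5.02% in the strongest quintile, where 92 peaks were 80 to 99 bp wide and 420 were 120 to 139 bp wide.

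**Figure D1:**
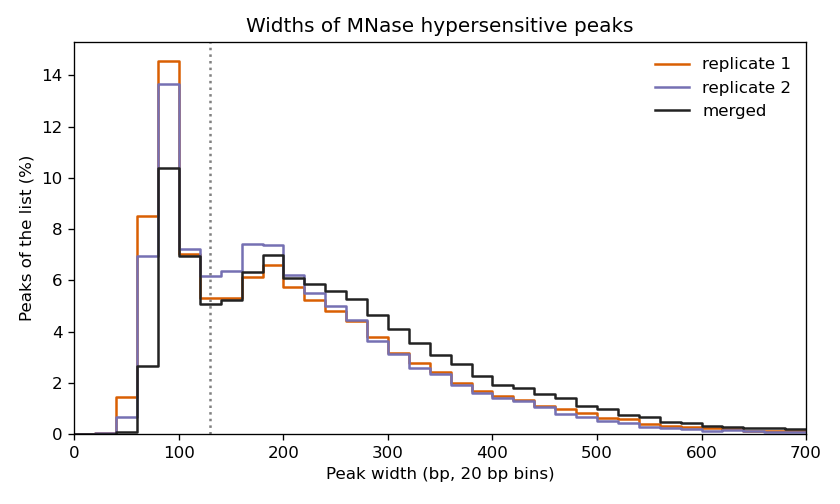
Widths of peaks in the 3 lists, as the percentage of each list per 20 bp bin; the dotted line marks 130 bp. All 3 curves have a maximum at 80 to 99 bp and a second, broader one between 160 and 199 bp; narrow peaks are 34.2% of replicate 1 and 22.8% of the merged list.

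The same sites recurred in both replicates far more often than random positions would. Of the replicate 1 peaks, 51750 (69.5%, Wilson 95% interval 69.2 to 69.8%) overlapped a replicate 2 peak, 59.0 times the 1.18% ± 0.0527 (SD over 1000 shifts) found after shifting the peaks (permutation p = 0.001, the smallest possible). Of the replicate 2 peaks, 52349 (86.5%, 86.2 to 86.8%) overlapped a replicate 1 peak, against 1.45% after shifting (permutation p = 0.001). The share was similar on each chromosome: it ran from 67.5% on chromosome 6 to 71.0% on chromosome 3 for replicate 1, and from 84.7% on chromosome 2 to 88.4% on chromosome 9 for replicate 2. With equal numbers of strongest peaks the 2 shares were 79.9% and 81.1%. Only 563 peaks had identical start and end in both lists, so the lists are not copies of one another.

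Recurrence depended on peak strength. In replicate 1, 25.3% (24.6 to 26.0%) of the weakest quintile and 98.2% (98.0 to 98.4%) of the strongest overlapped a replicate 2 peak. In replicate 2 the shares were 60.6% (59.7 to 61.5%) and 99.3% (99.1 to 99.4%). The 22693 peaks found in replicate 1 alone had a median width of 93 bp and a median fold enrichment of 5.70, against 225 bp and 9.08 for its shared peaks. The 8169 peaks found in replicate 2 alone had a median width of 92 bp and a median fold enrichment of 5.53, against 198 bp and 7.75. A peak of the other replicate lay within 200 bp of 9.72% of the peaks found in replicate 1 alone and of 18.0% of those found in replicate 2 alone.

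**Figure D2:**
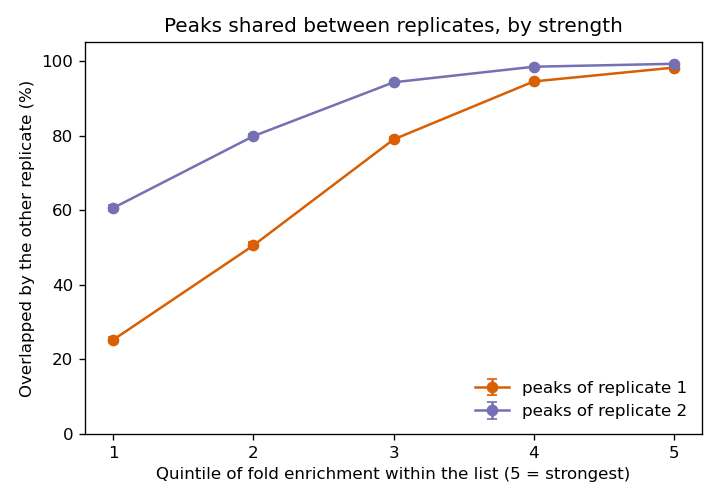
Percentage of peaks overlapped by the other replicate (at least 1 bp) by quintile of fold enrichment within each list; bars are Wilson 95% intervals. The share rises from 25.3% to 98.2% in replicate 1 and from 60.6% to 99.3% in replicate 2.

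Most merged peaks had a counterpart in both replicates. There were 51102 of them (76.5%, Wilson 95% interval 76.2 to 76.8%), with a median width of 252 bp and a median fold enrichment of 8.44. A further 10653 (15.9%) overlapped a peak of replicate 1 alone, 3887 (5.82%) one of replicate 2 alone, and 1159 (1.73%) overlapped neither list. Those 1159 peaks had a median width of 88 bp and a median fold enrichment of 5.14. Both replicates held a counterpart of 41.8% of narrow merged peaks (41.0 to 42.6%) and of 86.7% of wider ones (86.4 to 87.0%). By quintile of fold enrichment, from the weakest to the strongest, 10.9%, 46.6%, 81.9%, 93.0% and 97.2% of narrow peaks had a counterpart in both replicates, against 37.5%, 78.9%, 95.3%, 98.7% and 99.0% of wider ones. The quintiles are broad, so the classes were also compared within 200 groups of peaks of similar fold enrichment. This comparison was added after the data were seen. Group shares were averaged with weights from the numbers of narrow and wider peaks in each group. The average share with a counterpart in both replicates was 52.4% for narrow and 70.9% for wider peaks. The difference was -18.5 percentage points (permutation p = 0.001, with peaks as units). A wider peak meets the 1 bp overlap rule more easily, so the rule itself may contribute. Of the peaks found in replicate 1 alone 47.2% overlapped a merged peak, as did 49.1% of those found in replicate 2 alone. The merged list is for these same replicates, so its overlap with them is not independent evidence of recurrence. That overlap was not set against shifted peaks.

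The 10 strongest merged peaks were compact and were found in both libraries. The site with the highest fold enrichment lay on chromosome 2 at 176907365 to 176907536 (172 bp), with a fold enrichment of 93.9 in the merged list, 95.9 in replicate 1 and 93.8 in replicate 2; it ranked 1 in both. The next was on chromosome 7 at 46267171 to 46267296 (126 bp, fold enrichment 87.1), followed by chromosome 10 at 48840973 to 48841109 (137 bp, 79.6). A site near the end of chromosome 5 at 215772072 to 215772216 (145 bp) reached 61.9, and a second site on chromosome 7 at 38726636 to 38726803 (168 bp) reached 56.8. On chromosome 1, sites at 197011941 to 197012103 (163 bp), at 17091 to 17239 (149 bp, close to the chromosome start) and at 125698846 to 125699085 (240 bp) had fold enrichments of 49.5, 48.6 and 42.8. Another site on chromosome 7 at 155440277 to 155440455 (179 bp) had 44.3, and a second on chromosome 2 at 98044354 to 98044445 (92 bp) had 38.1. All 10 stood among the top 20 peaks of each replicate, and 9 were under 200 bp wide, while the median width in the strongest quintile of merged peaks was 286 bp. The 10 were chosen from the authors' list for both replicates, so their ranks in each replicate are not independent evidence of recurrence. Gene annotation of these positions was not analysed here. With no untreated or naked-DNA group and no sequence, whether their height reflects hypersensitivity or the underlying sequence was not tested.

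Called peaks were denser towards the chromosome ends than in the middle, except at the start of chromosome 6. No sequence was used, so mappability along the chromosomes was not examined. A gradient in detection is therefore not separated from a gradient in hypersensitive sites. The merged list held 41.3 ± 3.71 summits per Mb in the outer 20% at each end and 22.6 ± 4.18 per Mb in the middle 20% (mean ± SD over 10 chromosomes), a mean log2 ratio of 0.88 ± 0.30, or 1.84-fold. The ratio was above 0 on 10 of 10 chromosomes (exact sign-flip permutation p = 0.00195, the smallest possible), from 0.44 on chromosome 6 to 1.45 on chromosome 5. It was 0.82 in the replicate 1 list and 0.92 in the replicate 2 list. Taken singly, in a comparison added after the data were seen, the last 20% was denser than the middle on 10 of 10 chromosomes (mean log2 ratio 1.04 ± 0.21, exact sign-flip p = 0.00195) and the first 20% on 9 of 10 (0.68 ± 0.49, exact sign-flip p = 0.00586). The exception was chromosome 6, with 24.5 summits per Mb in its first 20%, 27.5 in the middle and 50.1 in its last 20%. The number of peaks per Mb over a whole chromosome varied little, from 29.0 on chromosome 4 to 33.2 on chromosome 9. The least dense decile of chromosome length was decile 3 or 4 on 7 chromosomes and decile 5 or 6 on the other 3. It held 8.07 summits per Mb on chromosome 7 (decile 4), 10.6 on chromosome 3 (decile 4) and 12.1 on chromosome 4 (decile 5). In 2 comparisons added after the data were seen, peaks were split by strength and by width. The strongest quintile of peaks was less concentrated at the ends (mean log2 ratio 0.61 ± 0.29) than the weakest (0.97 ± 0.34), with a difference of -0.36 ± 0.16 that was negative on 10 of 10 chromosomes (exact sign-flip p = 0.00195, adjusted 0.00391 over the 2). Narrow peaks were less concentrated at the ends (0.74 ± 0.32) than wider ones (0.93 ± 0.31), with a difference of -0.18 ± 0.19 that was negative on 8 of 10 chromosomes (exact sign-flip p = 0.0195, adjusted 0.0195). Among isolated peaks, with no other summit within 5 kb, the ratio was 0.65 ± 0.41 in the strongest quintile and 0.50 ± 0.25 in the weakest, a difference of 0.16 ± 0.30 (exact sign-flip p = 0.113).

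**Figure D3:**
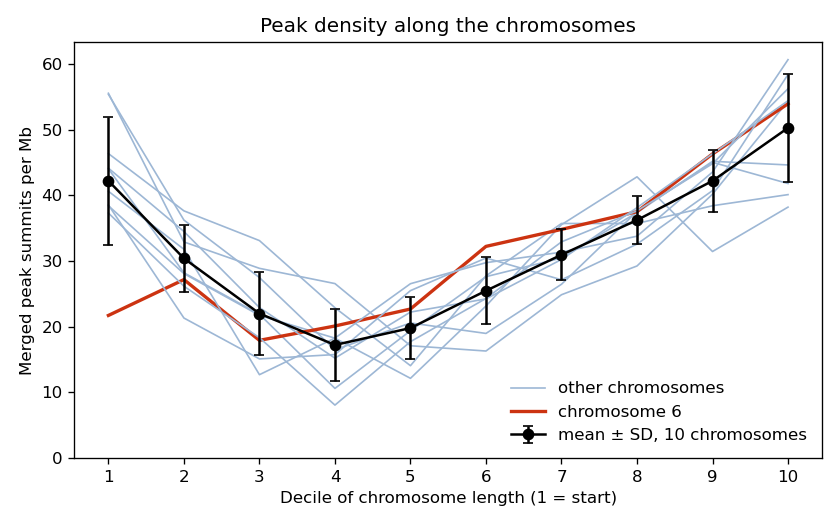
Merged peak summits per Mb in each decile of chromosome length, for each of the 10 chromosomes (thin lines, chromosome 6 in red) and as mean ± SD over chromosomes (black). The mean is lowest in decile 4, at 17.2 per Mb, and highest in decile 10, at 50.3; the first decile of chromosome 6 holds 21.7 per Mb against 54.0 in its last.

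Single windows of 1 Mb departed widely from the median of 31 merged peaks (interquartile range 21 to 41, 2101 windows). The densest was on chromosome 5 at 217000001 to 218000000, with 89 merged peaks, 94 peaks in replicate 1 and 77 in replicate 2. It was followed by chromosome 9 at 154000001 to 155000000 with 85, chromosome 5 at 5000001 to 6000000 with 83, chromosome 10 at 134000001 to 135000000 with 82 and chromosome 6 at 166000001 to 167000000 with 80. No merged peak fell in 3 windows: chromosome 6 at 12000001 to 13000000, chromosome 8 at 50000001 to 51000000 and chromosome 9 at 54000001 to 55000000. In these, replicate 1 held 1, 2 and 1 peaks and replicate 2 held 1, 0 and 1.

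Called peaks were clustered at short range. The next summit lay within 1 kb for 17.8% of merged summits, 5.69 times the 3.13% ± 0.0650 (SD over 1000 placements) of uniform placement (permutation p = 0.001, the smallest possible). Placement within the same 1 Mb windows, which keeps the excess at the chromosome ends, gave 3.70% (4.82-fold, permutation p = 0.001). Both placements used every base, whether or not a peak could be called there. Clustering of sites is therefore not separated from clustering of the sequence in which peaks can be called. The share was 18.2% in replicate 1 and 17.6% in replicate 2. Pairs of merged summits were most frequent at 400 to 499 bp, with 1566 pairs. There were 228 pairs at 4200 to 4299 bp, 267 at 4900 to 4999 bp, 349 at 5000 to 5099 bp and 410 at 5100 to 5199 bp. In all there were 2492 pairs 4 to 5 kb apart and 3790 pairs 5 to 6 kb apart, a ratio of 1.52 (exact 95% interval 1.45 to 1.60). The same ratio was 1.44 (1.38 to 1.51) in replicate 1 and 1.49 (1.41 to 1.58) in replicate 2.

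**Figure D4:**
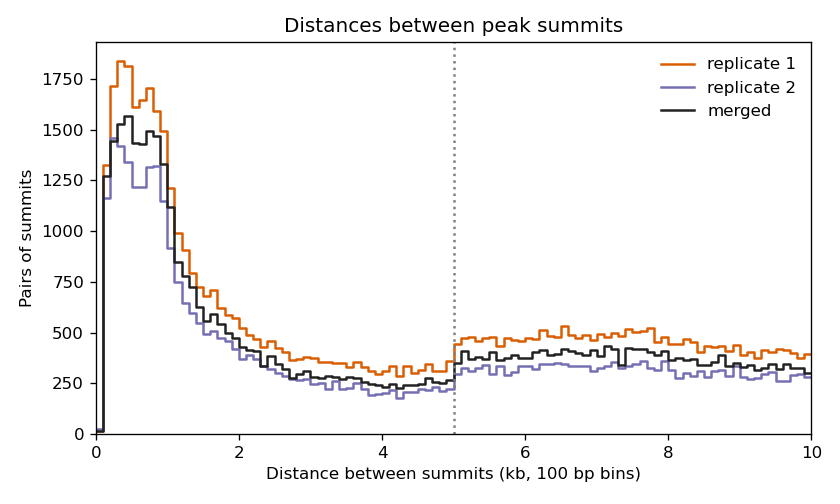
Number of pairs of summits per 100 bp of distance, within each of the 3 lists; the dotted line marks 5 kb. Each curve is highest below 1 kb, and each steps up at 5 kb, by 1.52-fold in the merged list when 5 to 6 kb is compared with 4 to 5 kb.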

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

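The permutation call on replicate overlap and its direction held under all 7 alternatives, with shares from 57.6 to 79.9% for replicate 1 and from 70.9 to 89.6% for replicate 2. The excess at chromosome ends held under all 10 alternatives (log2 ratio 0.61 to 1.10) and the clustering under all 9; its fold over placement, 5.69 as reported, was 2.34 within 5 kb (34.4% against 14.7% expected), 5.35 within 500 bp (8.45% against 1.58%), 4.82 with placement within the same windows, and 5.23 to 6.21 in the other 6; of these, the width, strength and same-window settings were chosen after seeing the data. The share of merged peaks found in both replicates moved to 68.3% with an overlap of at least 50% of both peaks, 63.8% with summits within 50 bp, 71.2% with −log10 q of at least 10 and 77.9% with peaks within 100 bp joined; in the third of these settings the filter acts on all 3 lists, and 11602 replicate 1 peaks fall below it against 1161 merged peaks. The mean of the median widths, 184.5 bp, moved to 203 bp with −log10 q of at least 10 and to 192 bp with joining, which widens peaks by construction; the peaks that the filter removed had median widths of 78 bp in replicate 1 and 82 bp in replicate 2. Leaving out either replicate gave 60518 to 74443 peaks. A −log10 q of at least 5 removed no peak and so tests nothing. Joining of peaks within 100 bp was not applied to the clustering. Its alternatives therefore do not address regions split into several peaks. Replicate overlap needs both libraries, so it has no value with one left out. The alternatives for annotated features, gene starts, gene lists and motifs were not run, for want of an annotation of the same build. No paired analysis was possible because the libraries form a single group. Depth is unknown; near the fold enrichment limit of 5, absence of a peak from a list does not show absence of hypersensitivity.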

Other observations

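The tests of strong peaks in the middle of chromosomes, of narrow minus wider peaks and of each quintile's change among isolated peaks were chosen after their results were seen; the others below were set before their own results were seen, on patterns already noticed in the data.

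The longest stretch of each chromosome without a merged summit started between 27.5 and 47.0% of the length on 9 chromosomes and, on chromosome 6, near its start. On those 9 it fell in the less dense part of the chromosome, and no gap length expected at that density was computed. The longest of these stretches ran for 2388 kb on chromosome 6, from 11074734 to 13462925, and held 2 summits of replicate 1 and 1 of replicate 2. The next were 1558 kb on chromosome 8 (49881038 to 51438677), 1483 kb on chromosome 9 (53675825 to 55158645), 975 kb on chromosome 7 (59933643 to 60908308) and 883 kb on chromosome 4 (98055883 to 98938740). A stretch of 652 kb on chromosome 2 (96719547 to 97371311) held no summit of either replicate. Chromosome 6 was also the least symmetric: its last decile held 2.48 times as many summits per Mb as its first, compared with 0.755 on chromosome 2 and 1.52 on chromosome 10. The short arm of chromosome 6 is the one that carries the nucleolus organizer in maize. Whether these stretches are unmappable, unassembled or closed was not tested, since no sequence was used.

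The 100 strongest merged peaks were not unusually frequent in the middle 20% of the chromosomes: 12 of them lay there, against 13.9% of all merged peaks (permutation p = 0.667, 1.00 after adjustment over 4 such tests). Among the 1000 merged peaks with the highest −log10 q, 174 did (17.4%, permutation p = 0.00599, adjusted 0.0240), whereas 143 of the 1000 with the highest fold enrichment did (permutation p = 0.789, adjusted 1.00). Unlike the end-to-middle tests, these did not take chromosomes as units, and peaks are not independent replicates.

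The step in summit spacing at 5 kb is a candidate effect of peak calling. The pattern was noticed at this distance, where the largest change in pair counts between 2 and 8 kb fell at 5000 bp in each of the 3 lists; that is also the reach of the 10 kb local background that MACS2 uses by default; the settings used here are not known. Pairs with a large peak (top quintile of fold enrichment times width) showed a ratio of 2.33 (exact 95% interval 2.09 to 2.60) across 5 kb, and pairs without one 1.33 (1.26 to 1.41), so the first was 1.75 times the second. This comparison is consistent with a background that a large neighbour raises, which would leave sites within 5 kb of a strong site under-called; the position itself prompted the idea and is no test of it. A biological arrangement at this distance was not tested and remains open.

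The strongest quintile of merged peaks was less concentrated at chromosome ends than the weakest, by -0.36 ± 0.16 in log2 end-to-middle ratio. The share of narrow peaks does not account for it. Among peaks of at least 130 bp the difference was -0.75 ± 0.35 (negative on 10 of 10 chromosomes, exact sign-flip p = 0.00195). Narrow minus wider peaks gave -0.18 ± 0.19, although narrow peaks were commoner in the weakest quintile. Widths among peaks of at least 130 bp were not matched between quintiles, so an effect of width in that range is not excluded. Whether a background raised by neighbouring peaks is the cause cannot be told apart from the effect of the filter used to test it: among isolated merged peaks, with no other summit within 5 kb, the difference was 0.16 ± 0.30 (negative on 4 of 10 chromosomes, exact sign-flip p = 0.113), but this came from the weakest quintile, which fell from 0.97 to 0.50 (change -0.47 ± 0.20, exact sign-flip p = 0.00195), while the strongest stood at 0.61 in all peaks and 0.65 in isolated ones (change 0.04 ± 0.18, exact sign-flip p = 0.494). Isolated peaks (40.3% of the list) leave out dense regions by design, which by itself can lower an end-to-middle ratio. The nearly level ratio of the strongest quintile therefore does not decide whether a raised background lowers strong peaks at the ends. The limit set beforehand ignored this effect of the filter. No biological explanation was tested.

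Among the strongest quintile of merged peaks, 264 pairs of summits lay 600 to 999 bp apart. That was 2.78 times (exact 95% interval 2.19 to 3.55) as many as at 200 to 599 bp and 2.93 times (2.30 to 3.77) as many as at 1000 to 1399 bp. The first ratio was 2.97 in replicate 1 and 2.20 in replicate 2. Peaks of a list do not overlap and these had a mean width of 313 bp, so part of the 200 to 599 bp class is closed to them. Over all merged peaks no such excess over shorter distances was seen, with 1566 pairs at 400 to 499 bp and 1492 at 700 to 799 bp. Whether the paired strong peaks are parts of one wide region split by peak calling cannot be told apart here. The median gap was 455.5 bp, but choosing pairs at this distance fixes a wide gap. No single 10 bp distance stood out by the limit set (the highest bin was 2.27 times the mean). Summits were not shown to be placed to 10 bp. Of all replicate 1 peaks, 57.6% had a replicate 2 summit within 50 bp, against 69.5% that overlapped. The precision of summits in the strongest quintile was not measured. If those summits vary by more than 10 bp, one repeated element of fixed length could spread over several bins. Neither it nor elements of varied length are therefore excluded. A short background window also stays open: pairs at 500 to 599 bp were 0.613 times (0.327 to 1.12) those at 400 to 499 bp (19 against 31), with no rise at 500 bp, but those at 600 to 699 bp were 2.37 times (1.36 to 4.29) those at 500 to 599 bp in the merged list, 1.33 times (0.787 to 2.28) in replicate 1 and 1.56 times (0.921 to 2.69) in replicate 2, where a rise is not resolved, and the limit set beforehand ignored peak width (mean 313 bp), which lets a neighbour over 600 bp away reach into such a window; the settings used are not known. A candidate explanation left open is a pair of hypersensitive sites at opposite borders of a recurrent unit under 1 kb long, such as a short gene, which needs the annotation to test.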
